A study of Homo sapiens with 4 samples.

How the data were processed

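Ribosome-protected mRNA fragments were measured in 4 libraries of Kasumi-1 cells, 2 from cells with an inducible shRNA against FBL and 2 from cells with a control shRNA. Per the labels' protocols, shRNA expression was induced with 100 ng/ml doxycycline, lysates were digested with RNase I, fragment ends were repaired with T4 polynucleotide kinase, and a small-RNA kit was used for the libraries. Groups and replicate numbers were taken from the sample titles.

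The authors deposited raw counts of footprints on the coding sequence of each transcript, in 67575 rows with a transcript identifier, a gene symbol and a coding length. The authors also deposited RPKM values for the same rows. In that table the RPKM values correspond to a library size of 97.3% to 102% of the column totals, so a scaled library size had been used. Per the submitters' processing notes, cutadapt 2.10, Bowtie2 and SAMtools were used, and the builds hg19 and GRCh38 were named without a role. The counter, the annotation release, the use of strand and the treatment of reads that match several transcripts were not given in the sources used here. All 67575 transcripts were found in GENCODE release 29, which gave the GRCh38 coordinates, and the coding length was equal in 98.8% of them. Among 2036 pairs of transcripts of the same gene with identical coding sequences and at least 100 counts, only 1.62% had equal counts, and the median relative difference was 6.20%. Footprints had therefore been divided among transcripts rather than counted on each.

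Rows without a gene symbol numbered 911 and held 0.843% to 0.933% of each library's counts; they were kept out of library sizes and tests. For each of the 13397 symbols the row with the largest summed count was kept, as fixed before the data were examined. These rows held 40.1% to 41.3% of all counts, so the main test used fewer than all footprints of a gene. Counts summed over all rows of a symbol were added as an alternative after the data had been seen, as were counts thinned to the shallowest library.

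The main test was edgeR 4.0.16 (R 4.3.3) with its default expression filter, TMM scaling and the quasi-likelihood test on counts, knockdown minus control, with Benjamini-Hochberg adjustment and a threshold of 0.05. After filtering, 8949 genes were tested and 4448 were not. Levels are given as TMM-scaled CPM of the kept rows, with the SD over 2 libraries. The common biological coefficient of variation was 4.71%. Where both control libraries held 0 counts, the fold change is given as a lower bound against a floor of 3 counts in each library, equal to 2.38 to 3.57 CPM in the controls and 1.41 to 1.56 CPM in the knockdown. Where a group held 1 count, the ratio is given with its exact 95% binomial interval. Both cover counting error only, because the reads carry no molecular identifiers.

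Replicates differed by more than sampling noise. A chi-square test of their counts over genes gave 1.56 per degree of freedom in the knockdown pair and 1.25 in the control pair, so no library was treated as a copy of another. Pearson's r of log2 CPM across genes was 0.985 and 0.972 within groups and 0.907 to 0.914 between same-numbered libraries of the 2 groups.

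Of 41 gene lists written before the data were examined, 38 had at least 4 tested members. These were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 38 lists. With a correlation estimated from the data, 0 of the 38 lists passed, and 1, the granulocyte list, had an unadjusted p under 0.05 (0.0483). That setting rests on the few degrees of freedom that 4 libraries leave and had little power. The large-subunit ribosomal proteins had an estimated correlation of -0.0185, below the preset value, yet their unadjusted camera p went from 0.00375 to 0.0728. For that list, failure with an estimated correlation therefore does not show that correlation between genes produced the call. The estimates were also below the preset for small-subunit proteins (-0.0169) and cholesterol (-0.0428). They were above it for histones (0.123), endoplasmic reticulum chaperones (0.0939), mitosis (0.0785), inflammatory genes (0.0345), the granulocyte list (0.0256) and 60S maturation (0.0188). The preset p-values of these lists may therefore be too small. fry, which asks whether a list's genes move on balance in one direction without comparing them with other genes, called 18. The share of footprints per list used all rows of the listed genes. No test was run on it; an exact two-sided permutation test of 2 against 2 libraries cannot give a p below 0.333.

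The genes named in the text follow a rule set before the data were examined. It takes FBL, then the 10 largest rises and 10 largest falls among changed genes with a mean count of at least 20 and no overlap between groups, then the 4 members with the smallest unadjusted p in each list that passed, then a fixed panel. Some genes that the rule takes, and a gene list added later, are not reported here. Other genes are marked as chosen after their values were seen.

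Both tests were tested on simulated data. In counts drawn for this comparison over 8684 genes with 200 given a change, edgeR recovered 50% of 66 genes changed by 1.5-fold, 60.6% of 66 changed by 2-fold and 98.5% of 66 changed by 4-fold, and 12 calls (8% of all calls) were false. When the proteasome list was shifted by 0.5 on the log2 scale, camera gave it an adjusted p of 5.9e-24 with the preset correlation and 0.264 with an estimated one, and called 0 of the other lists. Genes were drawn independently of each other, so this gives no rate of false list calls for correlated genes.

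Other settings chosen before the data were examined were other scalings (median-of-ratios, upper quartile, library totals, and TMM without mitochondrial, ribosomal protein and histone genes), no filter and a stricter filter (20 counts in at least 2 libraries and a mean of 50), DESeq2 1.42.0, limma-voom, edgeR's legacy fit, limma on log2(RPKM + 1) and log2(RPKM + 0.1), every row tested as deposited, the replicate number as a block, and each library left out in turn. For each list that passed, every member was also set against the 10 tested genes outside the list that were closest in GC content and log2 coding length. For genes with large changes, those with an adjusted p under 0.05 (exact binomial test of counts given the library sizes) and a log2 ratio of 3 or more in size in 1 knockdown and 1 control library were read in the other 2 libraries, thinned to equal depth, with 0.5 added to each count. Matched RNA-seq was not analysed here.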

Results

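Ribosome footprints were sequenced from Kasumi-1, a human acute myeloid leukaemia line that carries the RUNX1-RUNX1T1 fusion gene. The cells expressed a doxycycline-inducible shRNA against FBL or a control shRNA and were collected after 3 days of induction, with 2 libraries per group. FBL (fibrillarin) is the methyltransferase of the box C/D small nucleolar ribonucleoprotein, which places 2'-O-methyl groups on ribosomal RNA. The comparison asks which mRNAs carried more or fewer ribosomes once FBL was depleted. The knockdown libraries held 4651571 and 5154876 footprints on coding sequences and the control libraries 2127879 and 3194181, so low levels were measured less precisely in the controls. Footprint levels depend on both mRNA amount and translation, and the 2 were not separated here. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical, and the shRNA cannot be told apart from other differences between the cell populations.

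FBL itself fell. On its most covered transcript (ENST00000595545; GRCh38 chromosome 19, 39834458 to 39840441) the level was 7.32 ± 2.24 CPM in the knockdown and 89.6 ± 2.09 CPM in the control (SD, n = 2 each). The log2 fold change was -3.59 (SE 0.23; adjusted p = 1.31e-18, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Summed over all 9 FBL transcripts, 9.33% of the control level was left, with 90 and 99 footprints in the knockdown libraries and 427 and 599 in the controls. Among FBL's partners in the box C/D core, NOP56 rose (log2 fold change 0.82, SE 0.13), while NOP58 (0.12, SE 0.11) and SNU13 (0.07, SE 0.16) did not pass. The list of 4 core proteins includes FBL, the shRNA target. It held 1 gene that rose and 1 that fell, FBL itself, also when adjusted over the list alone. Its median was 0.10, its mean, with FBL counted, -0.64, and its downward test did not pass (camera adjusted p = 0.975). Of 9 assembly factors of this complex, 3 rose and 0 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.321).

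Footprints changed on 2835 of 8949 tested genes (31.7%), of which 1321 rose and 1514 fell. At least a 2-fold change was fitted for 426 of the genes that rose and 493 of those that fell, and a log2 change of 3 or more for 55 and 65. The knockdown and control libraries did not overlap for 2816 of the changed genes and for 64.0% of all tested genes, against 33.3% by chance. The number of changed genes ranged from 1087 with DESeq2 to 4359 with counts summed over all transcripts of a gene, and was 1657 without control replicate 2. Scaling by library totals alone gave 1793 genes that rose and 1179 that fell (60.3% of calls rose, against 46.6%), with the median of all genes at 0.12 in place of 0.01.

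Of the 10 largest rises, 6 were of genes with 0 footprints in both controls on the kept transcript. Footprint counts and ratios of single genes refer to that transcript unless summed transcripts are named. Footprints on other transcripts of these genes are not excluded. ARID5B, a DNA-binding transcriptional regulator, reached 52.1 ± 7.42 CPM in the knockdown with 0 footprints in both controls, at least 17.5-fold higher. The others were SLC18A2, the vesicular monoamine transporter (at least 14.7-fold higher), the adhesion receptor ADGRG3 (9.57), the tyrosine kinase BMX (9.01), the let-7 antagonist LIN28B (7.62) and THSD1 (6.72), each given as a lower bound. PPP1R27 had 1 control footprint and a ratio of 255 (95% interval 45.5 to 10083), and PTPRCAP 1 control footprint and a ratio of 87.7 (15.5 to 3484). TRDC, the constant region of the T cell receptor delta chain, rose from 2.77 ± 0.556 to 149 ± 0.657 CPM. IGLL1, the surrogate immunoglobulin light chain (chromosome 22, 23573125 to 23580308), rose from 11.3 ± 2.54 to 472 ± 4.89 CPM (log2 fold change 5.42, SE 0.16). THSD1 and PTPRCAP overlap VPS36 and CORO1B on the same strand, and SLC18A2 and BMX overlap genes on the opposite strand, so their reads are uncertain where counting did not keep them apart.

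MNDA, the myeloid nuclear differentiation antigen (chromosome 1, 158831317 to 158849504), had the largest fall, from 724 ± 2.94 to 1.22 ± 0.257 CPM (log2 fold change -9.11, SE 0.18; adjusted p = 4.66e-41, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). LGR4, a receptor for R-spondins, fell from 300 ± 30.9 to 2.21 ± 0.182 CPM, and WDFY4 from 648 ± 9.25 to 5.13 ± 1.36 CPM. SESN3, a stress-responsive regulator of mTORC1, fell from 125 ± 14.1 to 0.99 ± 0.0747 CPM. The protease inhibitor SERPINA1 had a log2 fold change of -5.31 (SE 0.17), the integrin subunit ITGA9 -4.86 (SE 0.27), the semaphorin co-receptor NRP2 -4.76 (SE 0.30) and the kinase SYK -4.64 (SE 0.26). WDFY4 overlaps an antisense gene.

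**Figure D1:**
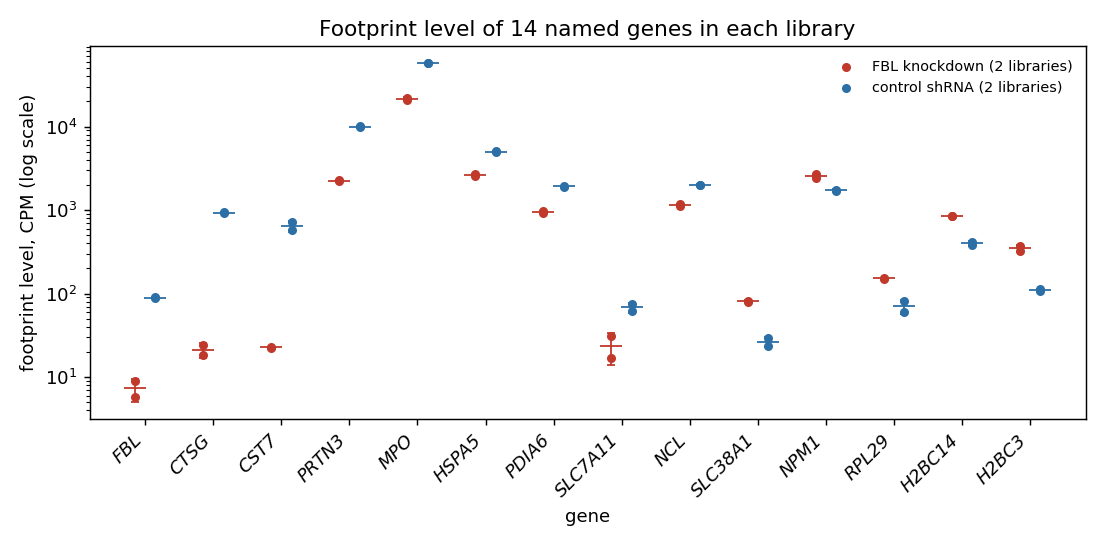
Footprint CPM (log axis) of 14 named genes in each of the 2 knockdown and 2 control libraries; points are libraries, horizontal marks are group means and bars are SDs. FBL lies at 7.32 CPM in the knockdown against 89.6 in the control, and for each of the 14 genes both knockdown libraries lie on the same side of both controls.

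Granule proteins and other genes of the granulocyte lineage lost footprints. Of 17 tested members of the list 11 fell, 1 rose and 5 did not pass (12 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -0.77 and a camera adjusted p of 1.73e-05 (adjusted p = 0.566 with an estimated correlation). The serine protease CTSG fell by 5.43 on the log2 scale (SE 0.11), the protease inhibitor CST7 by 4.83 (SE 0.13) and the serine protease PRTN3 by 2.16 (SE 0.05). MPO, the myeloperoxidase of azurophil granules (chromosome 17, 58269856 to 58280935), fell by 1.42 (SE 0.04), and its share of all footprints was 0.954% ± 0.0475 in the knockdown against 2.42% ± 0.00431 in the control. MPO, PRTN3 and ELANE, the latter chosen after its values were seen, together held 1.37% ± 0.0599 against 3.70% ± 0.00599. The member that rose was CSF3R, the receptor for granulocyte colony-stimulating factor (chosen after its values were seen). Its kept transcript had 42 footprints against 1 (ratio 21.8, 95% interval 3.70 to 881).

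Markers of other blood cells moved in different directions or were scarcely detected. Of 6 tested monocyte and macrophage markers 4 fell and 1 rose, the same counts adjusted over the list alone (camera adjusted p = 0.165). Their median was -1.61 and their mean -0.24. The median stayed at -1.61 with the member that rose, MS4A7 (chosen after its values were seen), at its lower bound of 2.23-fold. The kept transcript of MS4A7 had 27 footprints against 0. The monocyte list passed with adjusted p = 0.00628 without knockdown replicate 1 and 0.00127 without knockdown replicate 2, and also with summed transcripts (0.0124) and at equal depth (0.015). The lymphoid list had 1 tested member of 21, CD4 (log2 fold change -2.12; chosen after its values were seen), and its summed share was 0.00363% ± 0.000452 in the knockdown against 0.0124% ± 0.000678. It did not hold the lymphoid receptor genes TRDC and IGLL1, which were among the largest rises. No member of the mast cell and basophil list (9 genes) or of the erythroid and megakaryocyte list (19 genes) was tested; their shares were 0.000443% ± 1.76e-05 and 0.00062% ± 7.41e-05 in the knockdown against 0.000182% ± 0.00019 and 0.000324% ± 0.000145 in the control, where the mast cell share was 4.74e-05% and 0.000316% in the single libraries. Among 15 transcription factors and receptors of stem and progenitor cells, 6 rose and 0 fell (6 and 1 adjusted over the list alone), with a median of -0.08, a mean of 0.35 and an upward test that did not pass (camera adjusted p = 0.418). KIT (log2 fold change -0.08, SE 0.05), RUNX1T1 (-0.16, SE 0.25) and CEBPA (-0.26, SE 0.25) did not pass. With summed transcripts KIT (-0.12) and RUNX1T1 (-0.27) fell, and CEBPA, with 18 and 73 footprints in the controls, fell without control replicate 1 (-0.69, adjusted p = 0.0499, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The sign of CEBPA turned without control replicate 2 (0.74) and without knockdown replicate 2 (0.10), values that did not pass. Of 6 tested genes of a leukaemia stem cell score 2 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.320). CD34 had too few footprints on its kept transcript to test (7 and 11 in the knockdown, 0 and 2 in the control).

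Chaperones, folding enzymes and stress-response factors of the endoplasmic reticulum fell together. Of 21 tested genes 15 fell, 2 rose and 4 did not pass (16 fell and 2 rose adjusted over the list alone), with a median of -0.79 and a camera adjusted p of 3.44e-06 (adjusted p = 0.566 with an estimated correlation). HSPA5, the luminal Hsp70 chaperone BiP, fell from 4992 ± 103 to 2636 ± 91.8 CPM (log2 fold change -0.92, SE 0.05). The disulfide isomerases PDIA6 and PDIA4 fell by 1.01 (SE 0.06) and 0.89 (SE 0.06) on the log2 scale, and calreticulin (CALR) by 0.69 (SE 0.05). The members that rose were SEC61B, a subunit of the translocon (0.64), and the stress sensor ATF6 (0.34), both chosen after their values were seen. The list took 1.13% ± 0.0326 of footprints in the knockdown and 1.83% ± 0.0016 in the control. Of 25 genes of cytosolic chaperones and the heat shock response 3 rose and 10 fell, also adjusted over the list alone (camera adjusted p = 0.619), and of 31 proteasome subunits 11 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.221).

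Genes of cholesterol synthesis and of the NF-kB response fell. Of 21 cholesterol genes 8 fell and 0 rose (9 and 0 adjusted over the list alone; median -0.29; camera adjusted p = 0.025, and adjusted p = 0.566 with an estimated correlation). The isomerase IDI1 fell by 0.84 (SE 0.11), the transcription factor SREBF2 by 0.73 (SE 0.12), and the sterol enzymes SC5D and CYP51A1 by 0.88 (SE 0.23) and 0.49 (SE 0.12), calls that ended with DESeq2 (adjusted p = 0.132 and 0.102), that of CYP51A1 also on log2(RPKM + 1) without a filter (limma adjusted p = 0.0508). Of 6 tested NF-kB response genes 3 fell and 0 rose, also adjusted over the list alone (median -0.77; camera adjusted p = 0.025, and adjusted p = 0.566 with an estimated correlation). These were the adhesion molecule ICAM1 (-3.38, SE 0.50), NFKB1 (-1.05, SE 0.17) and the chemokine CXCL8 (-1.12, SE 0.42); NFKB2 had -0.41 (SE 0.28). The cholesterol call ended with limma-voom (adjusted p = 0.0596), without knockdown replicate 2 (0.0595) and without control replicate 2 (0.0591). The inflammatory call ended with limma-voom (0.108), with summed transcripts (0.081), without knockdown replicate 1 (0.0636) and without control replicate 2 (0.0907), and that of CXCL8 ended in 7 of 18 alternatives, among them each left-out library (-0.81 to -1.30). Of 18 interferon-stimulated genes 5 rose and 8 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.221), a list that passed downward without a filter on low counts (0.0131) and on log2(RPKM + 1) without a filter (0.0133). Of 11 immediate early genes 1 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.221).

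Ribosomal proteins and 60S maturation factors gained footprints. Of 47 large-subunit proteins 23 rose and 7 fell (24 and 7 adjusted over the list alone; median 0.22; camera adjusted p = 0.0237, and adjusted p = 0.566 with an estimated correlation), and of 33 small-subunit proteins 17 rose and 1 fell (17 and 2 adjusted over the list alone; median 0.18; camera adjusted p = 0.025, and adjusted p = 0.566 with an estimated correlation). Examples are RPL29 (log2 fold change 1.07, SE 0.14), RPL31 (0.88, SE 0.07), RPL38 (0.64, SE 0.07), RPL8 (0.48, SE 0.06), FAU (0.78, SE 0.08) and RPS25 (0.69, SE 0.09). The small-subunit protein that fell was RPS12 (-0.21; chosen after its values were seen). Of 45 factors of 60S maturation 18 rose and 3 fell (19 and 4 adjusted over the list alone; median 0.24; camera adjusted p = 0.0146, and adjusted p = 0.566 with an estimated correlation). The methyltransferase FTSJ3 (1.20, SE 0.10), NOC2L (0.95, SE 0.13) and nucleophosmin NPM1 (0.56, SE 0.06) rose. Nucleolin (NCL) fell from 1999 ± 36.8 to 1150 ± 40 CPM (-0.80, SE 0.06), as did SDAD1 (-0.54) and NOP14 (-0.36), the latter pair chosen after their values were seen. The list as written is broader than its name, since NOP14 is a factor of 40S maturation and NCL is not specific to the 60S subunit. Both ribosomal protein calls ended without control replicate 1 (adjusted p = 0.0677 and 0.097), and all 3 without control replicate 2 (0.0921 each).

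Other parts of the translation machinery changed in both directions, and none of their lists passed in the main test. Of 42 factors of 40S maturation 9 rose and 3 fell (camera adjusted p = 0.318), of 6 box H/ACA proteins 2 rose and 1 fell (0.639), and of 23 further 5' oligopyrimidine transcripts 12 rose and 4 fell (0.321), each with the same counts adjusted over the list alone. The pseudouridine synthase DKC1 rose (0.28, SE 0.10), a call that ended in 9 of 20 alternatives, among them without knockdown replicate 2 (0.22) and without either control (0.28 each). Of 15 RNA polymerase I genes 1 rose and 2 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.320). Of 35 initiation factors and poly(A)-binding proteins 11 rose and 9 fell (13 and 9 adjusted over the list alone; 0.466). Of 15 genes in the list of elongation and termination factors 8 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.130). The list passed upward with limma-voom (camera adjusted p = 0.00528). Its median was 0.31, and it took 2.19% ± 0.0121 of footprints in the knockdown and 1.79% ± 0.000544 in the control. Its largest rise was that of EEF1E1 (3.03), a factor of the multi-synthetase complex and not an elongation factor, and it also held TPT1 (0.64), which binds elongation factors (both chosen after their values were seen). Of 23 genes of aminoacyl-tRNA synthetases and the multi-synthetase complex, EEF1E1 among them, 4 rose and 6 fell, also adjusted over the list alone, with a median of -0.09 and a mean of 0.02 (camera adjusted p = 0.660). Mitochondrial ribosomal proteins gave 6 rises and 3 falls of 47 in the large subunit (4 and 2 adjusted over the list alone; 0.321) and 7 and 2 of 27 in the small subunit (also over the list alone; 0.320).

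Replication-dependent histones rose together. Of 51 tested genes 42 rose, 0 fell and 9 did not pass (44 and 0 adjusted over the list alone), with a median of 0.58 and a camera adjusted p of 6.22e-11 (adjusted p = 0.566 with an estimated correlation). H2BC3 (chromosome 6, 26043277 to 26043657) rose from 110 ± 2.89 to 351 ± 34.2 CPM, a log2 fold change of 1.66 (SE 0.11). H2BC14 rose by 1.07 (SE 0.07), H2BC8 by 0.80 (SE 0.06) and H2AC11 by 0.71 (SE 0.05) on the log2 scale. Histone genes have near-identical copies, so single members are uncertain; their summed share was 3.81% ± 0.108 in the knockdown and 2.65% ± 0.0527 in the control. Genes outside the list with similar GC content and coding length had a median of 0.32. Such matched genes had medians of 0.10 for the large-subunit proteins, 0.03 for the small-subunit proteins and -0.02 for the endoplasmic reticulum chaperones.

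Mitotic genes fell slightly. Of 42 tested genes 19 fell and 1 rose (22 and 2 adjusted over the list alone), with a median of -0.24 and a camera adjusted p of 0.0131 (adjusted p = 0.566 with an estimated correlation). TOP2A fell by 0.55 (SE 0.05), the spindle assembly factor TPX2 by 0.52 (SE 0.07), the midzone protein PRC1 by 1.10 (SE 0.17) and the proliferation marker MKI67 by 0.40 (SE 0.07), a call that ended on log2(RPKM + 1) without a filter (limma adjusted p = 0.0564). The kinase AURKA rose (0.53; chosen after its values were seen). The list call ended without knockdown replicate 1 (adjusted p = 0.0563). Of 41 genes of DNA replication and the G1/S transition 6 rose and 11 fell (7 and 11 adjusted over the list alone; camera adjusted p = 0.418).

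**Figure D2:**
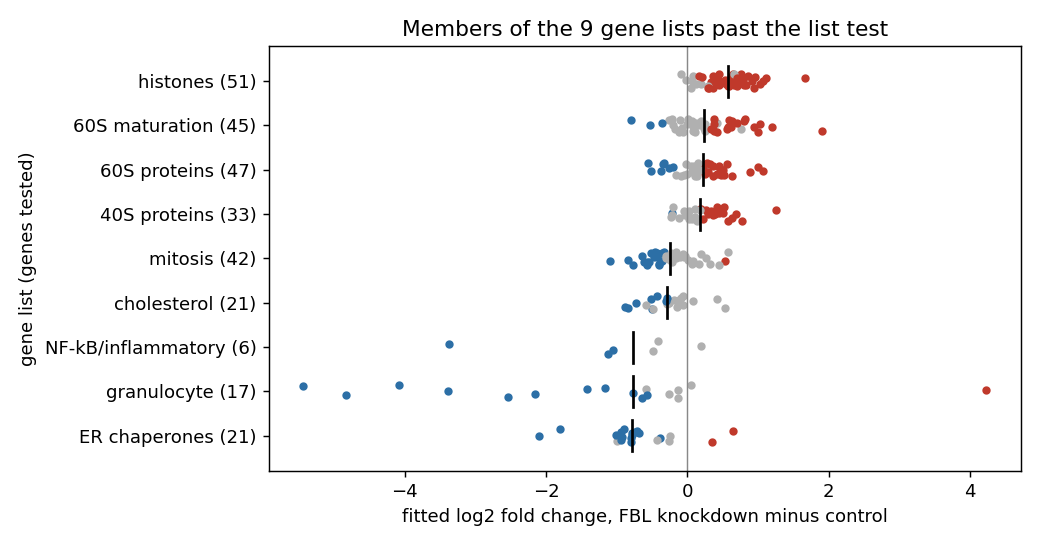
Fitted log2 fold change of each tested member (points) of the 9 gene lists past the list test, with the number of genes tested in parentheses; red and blue points rose or fell in edgeR's test, grey points did not pass, and black lines are list medians. Medians run from -0.79 for the endoplasmic reticulum chaperones to 0.58 for the histones.

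Amino acid transporters and stress genes were examined as a fixed panel. The cystine transporter SLC7A11 fell by 1.51 (SE 0.21) and the glutamine transporters SLC1A5 and SLC38A2 by 0.51 (SE 0.08) and 0.41 (SE 0.10), while SLC38A1, another glutamine transporter, rose from 26.6 ± 3.88 to 80.8 ± 2.27 CPM (1.58, SE 0.19). SLC7A5 (-0.07, SE 0.11) and SLC3A2 (-0.27, SE 0.13), the subunits of a leucine transporter, did not pass, although SLC3A2 fell with summed transcripts (-0.24), without knockdown replicate 2 (-0.36) and without control replicate 2 (-0.46). The call of SLC38A2 ended in 5 of 20 alternatives, among them without control replicate 2 (-0.30). Of 18 amino acid transporters 2 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.163). ATF4 fell by 0.79 (SE 0.21), a call that ended with DESeq2 (adjusted p = 0.171) and without control replicate 1 (edgeR adjusted p = 0.057), and of 19 genes of the ATF4 response 1 rose and 5 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.274). Of 12 serine and one-carbon enzymes 0 rose and 3 fell (0 and 4 adjusted over the list alone; camera adjusted p = 0.102).

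The panel also held genes of growth and survival. MYC (log2 fold change 0.09, SE 0.08), MCL1 (-0.08, SE 0.11) and BCL2 (0.99, SE 0.54) did not pass. BCL2 rose with summed transcripts (0.89), while its value without control replicate 1 was 2.22 and without control replicate 2 0.094, neither of which passed. CCND2 rose by 0.29 (SE 0.08), a call that ended in 9 of 20 alternatives, among them without knockdown replicate 1 (0.12) and without either control (0.30 and 0.27). Of 25 MYC targets 5 rose and 8 fell (6 and 8 adjusted over the list alone; camera adjusted p = 0.418). Of 17 p53 targets 3 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.320). MDM2 had -0.08 (SE 0.54) on 11 control footprints and rose by 0.57 when its transcripts were summed. Leaving out a library gave values from -0.75 (without control replicate 2) to 0.63 (without control replicate 1) for MDM2, none of which passed. CDKN1A had too few footprints on its kept transcript to test (5 and 3 in the knockdown, 1 and 2 in the control). Of 17 genes of the BCL2 family, caspases and their regulators 3 rose and 2 fell, also adjusted over the list alone, with a median of -0.06 and a mean of 0.12 (camera adjusted p = 0.806). Of 20 genes of glycolysis and glucose or lactate transport 7 rose and 2 fell (9 and 4 adjusted over the list alone; 0.418), of 76 nuclear respiratory chain genes 17 rose and 11 fell (0.619) and of 16 selenoproteins 2 rose and 2 fell (0.959), these last lists with the same counts adjusted over the list alone. Of 13 mitochondrially encoded genes 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.744); they took 0.295% ± 0.0811 of footprints in the knockdown and 0.267% ± 0.0397 in the control, a difference within the spread.

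**Figure D3:**
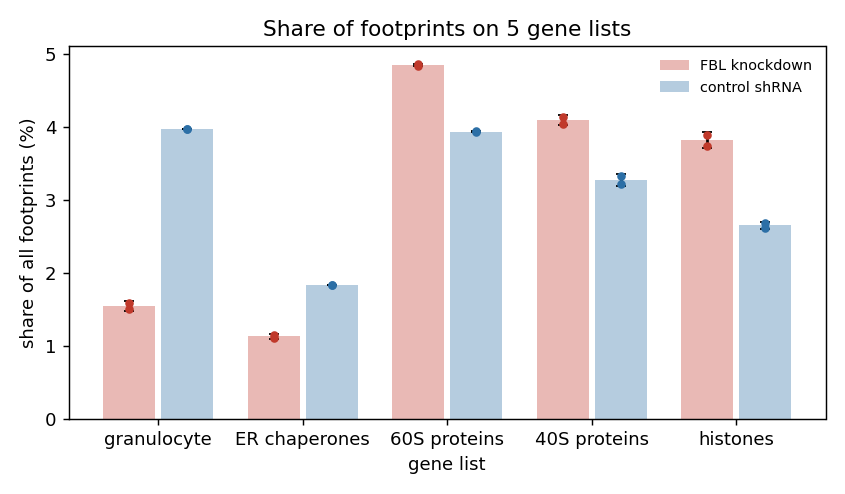
Share of all footprints (percent, axis from 0) on 5 gene lists; bars are means of 2 libraries, error bars SDs and points single libraries. The granulocyte list held 1.54% in the knockdown against 3.97% in the control, and the histones 3.81% against 2.65%.

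Across genes, the fold change leaned weakly on coding length. Spearman's rho of the log2 fold change with log2 coding length was -0.15 over 8949 genes (-0.21 with the stricter filter on low counts) and with mean log2 CPM -0.07 (-0.04); genes are not independent replicates, so no p-value is given. Large-subunit ribosomal proteins, which are short, took 4.84% ± 0.0157 of footprints in the knockdown and 3.93% ± 0.00976 in the control, and small-subunit proteins 4.09% ± 0.0716 and 3.27% ± 0.085.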

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

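Rows of the count table without a gene symbol were not part of any comparison. They held 0.928% ± 0.00656 of counts in the knockdown libraries and 0.850% ± 0.0097 in the controls (SD, n = 2 each), with both knockdown libraries above both controls, which is why they are listed here. The transcript with the most counts among them, AL031777.3 in GENCODE, held 0.089% ± 0.000348 of counts in the knockdown and 0.0532% ± 0.000116 in the control.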

How the results depend on the processing

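Summed transcripts and the equal-depth counts were chosen after the data had been seen; all other alternatives were planned. FBL fell under every alternative in which it was tested (log2 fold change -3.94 to -3.24). The number of changed genes, 2835 in the main test, was 1087 (421 rose, 666 fell) with DESeq2, 1731 (833 and 898) on log2(RPKM + 0.1), 1543 (749 and 794) on log2(RPKM + 1) without a filter, 8531 transcripts (3900 and 4631) when every row was tested, 4359 (2060 and 2299) with summed transcripts and 1791 (835 and 956) at equal depth. Genes that fell numbered 989 with the stricter filter and 970 on log2(RPKM + 1) with the filter. Leaving out a library gave 1657 to 2528 changed genes (725 to 1181 rose, 932 to 1347 fell), fewest without control replicate 2. These settings also changed how many features were tested (4595 to 33948, against 8949), and the cause of the differences was not tested. Of the 2835 genes, 93.7% kept their call and direction with summed transcripts, 61.1% at equal depth and 37.8% with DESeq2.

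The preset list test called 9 lists, an estimated correlation 0, fry 18, and leaving out a library 4 to 9 (4 without control replicate 2). With an estimated correlation, a setting with little power at 4 libraries, each of the 9 had an adjusted p of 0.566. limma-voom ended the cholesterol (0.0596) and inflammatory (0.108) calls and gave an upward call of the elongation and termination list (0.00528), and summed transcripts ended the inflammatory call (0.081). The interferon list passed downward without a filter (0.0131) and on log2(RPKM + 1) without a filter (0.0133). Over left-out libraries the adjusted p ranged from 0.00952 to 0.0563 for mitosis, 0.0125 to 0.0921 for 60S maturation, 0.023 to 0.0921 for large-subunit proteins, 0.0274 to 0.097 for small-subunit proteins, 0.0279 to 0.0595 for cholesterol and 0.0191 to 0.0907 for inflammatory genes. Histones, endoplasmic reticulum chaperones and the granulocyte list passed under all alternatives in which lists were tested, except the estimated correlation. Lists were not tested with DESeq2 or with every row as deposited. No called list changed direction.

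The replicate numbers do not pair the samples: deviations of same-numbered libraries had a correlation of -0.04 over 2 pairs. With the replicate number as a block 2793 genes changed, and the small-subunit list had an adjusted p of 0.0511. MDM2, not called in the main test, rose with summed transcripts (0.57). With sums of RPKM in place of counts the knockdown-to-control ratio of shares was 0.361 (main 0.389) for the granulocyte list, 1.32 (1.44) for histones, 1.15 (1.23) and 1.16 (1.25) for large- and small-subunit proteins, and 0.989 (1.11) for mitochondrially encoded genes, whose order turned. The stricter filter moved rho with coding length from -0.15 to -0.21 and with abundance from -0.07 to -0.044. Of the results for named genes under all alternatives, 1417 kept their side of the threshold, 36 lost the call, 7 gained it and 1, MDM2 with summed transcripts, passed in the other direction; values past the threshold in neither setting count as kept whatever their sign. At the depth and replicate number of this comparison, simulated 1.5-fold changes were found in 50% of cases and 4-fold changes in 98.5%. The simulation changed only 200 genes, against 2835 called here, and drew genes independently, so these rates may not carry over to the data.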

Other observations

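The lists of this part, the genes named from them or from chromosome 6, the test of S-phase genes and the test in left-out library pairs were chosen after the results had been seen. Bootstrap intervals in this part resample genes, which are not independent replicates, so they do not cover the spread between libraries. The added lists were tested on the same data that prompted them, so their p-values describe these data and are no independent support. The integrin and adhesion list, for example, held ITGA9, NRP2 and ICAM1, whose falls are given above. Genes of antigen presentation and of lysosomes lost footprints. Of 13 genes of MHC class I molecules and their peptide loading and regulation 9 fell and 0 rose (median log2 fold change -1.08; camera adjusted p = 3.96e-06 over 6 added lists, and adjusted p = 0.138 with an estimated correlation), led by B2M and HLA-B. Of 28 lysosomal genes, most of them hydrolases with some membrane proteins and activators, 16 fell and 1 rose (median -0.61; camera adjusted p = 2.95e-05, and adjusted p = 0.138 with an estimated correlation), led by the cathepsins CTSC and CTSZ. Of 34 genes for translocation and N-glycosylation in the endoplasmic reticulum 17 fell and 4 rose (median -0.27; camera adjusted p = 0.0109, and adjusted p = 0.138 with an estimated correlation). Genes of vesicle coats, cargo receptors and Golgi factors gave 8 falls and 4 rises of 32 (camera adjusted p = 0.0329), and integrins and adhesion genes 5 falls and 1 rise of 10 (camera adjusted p = 0.0115). The last pair of lists also had an adjusted p = 0.138 each with an estimated correlation, and the MHC class II list had too few tested genes.

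On chromosome 6, EEF1E1 (8079395 to 8102578), a factor of the multi-synthetase complex, rose from 39.4 ± 3.58 to 326 ± 1.91 CPM (log2 fold change 3.03, SE 0.13), and SLC35B3 (8413094 to 8435611) from 4.56 ± 1.97 to 39.6 ± 9.57 CPM (3.20, SE 0.37). BLOC1S5 (2.93) and the read-through gene EEF1E1-BLOC1S5 (2.89) share sequence with EEF1E1 or with each other, but SLC35B3 does not overlap them. Of the other tested genes within 2 Mb, SNRNP48 (1.38) and the read-through gene BLOC1S5-TXNDC5 (1.98), which shares sequence with BLOC1S5 and TXNDC5, rose. TXNDC5 (-0.97), RREB1 (-0.56) and SSR1 (-0.35) fell, F13A1 (6144085 to 6320834) fell from 9.91 ± 2.82 to 0.521 ± 0.737 CPM, and RIOK1 (-0.21) did not pass. By chromosome, the median log2 fold change ran from -0.15 on chromosome 4 (72 fell, 32 rose) and -0.14 on chromosome 2 (171 and 60) to 0.10 on chromosome 19 (69 and 90) and 0.12 on chromosome 6 (72 and 111). Without its 46 tested histone genes chromosome 6 had a median of 0.07 (72 fell, 73 rose).

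Near-complete gains and losses were fitted for 120 genes with a log2 change of 3 or more in size. If a copy-number difference between the cell populations were the cause, neighbours within 1 Mb would move along. The median of their signed log2 fold changes was 0.0877 (95% bootstrap interval 0.0419 to 0.133). Neighbours that were themselves among the 120 genes were left out, so pairs such as EEF1E1 and SLC35B3 could not count. For these genes as a set, the values argue only against a large shift shared with neighbours outside the 120. The median also exceeded the highest of 200 random gene sets (0.0831), so a regional component stays open. The test planned in advance did not decide on depth: after thinning to equal depth 59.2% of the 120 genes kept their call (29 rises and 42 falls), between the bounds of under 50% for a depth cause and 80% or more against it; the other 49 were all below the filter on low counts, and their median signed log2 ratio was 4.04 (95% bootstrap interval 3.91 to 4.79) before and 4.28 (3.57 to 5.15) after. In the test chosen afterwards, the values argue against the depth gap for the rises and the falls: genes picked for such changes in 1 knockdown and 1 control library had, in the other 2 libraries at equal depth, a median signed log2 ratio of at least 3.46 for rises (4 choices of libraries; lowest interval bound 2.99) and 3.53 for falls (3.06), above the largest ratio of library sizes (1.35 on the log2 scale), and these choices took 54 of the 55 rises and all 65 falls. A difference that existed before induction cannot be told apart from the knockdown, because 0 of the 4 libraries were uninduced.

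The rise of histone genes is open to a technical and a biological reading. Reads shared between copies cannot account for it, since the summed share of all histone rows rose by 0.53 on the log2 scale. GC content and coding length may contribute: matched genes outside the list had a median of 0.32, and the histones lay 0.25 above them (95% bootstrap interval 0.109 to 0.38), between the bounds set for a full and for no explanation. With a larger S-phase share, genes of DNA replication and the G1/S transition would rise too. Their median was -0.11 (95% bootstrap interval over genes -0.207 to -0.045), below the 0.58 of the histones. Their summed share was 0.802% ± 0.00304 in the knockdown and 0.862% ± 0.00137 in the control. As a set, this list did not rise with the histones. Its members went both ways (6 rose and 11 fell) and the list test did not pass, so these values do not decide on a larger S-phase share. An effect of the knockdown stays open.

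The fall of endoplasmic reticulum chaperones is not explained by GC content and coding length, because matched genes had a median of -0.0191 and the chaperones lay 0.77 below them (95% bootstrap interval 0.495 to 0.91). A candidate explanation is a lower load of secretory proteins, which would lower the import machinery too. Its median was -0.27 (-0.393 to -0.0554), just short of the bound of -0.3 set in advance, so this stays open, as does an effect of the FBL knockdown itself.

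A preference of the remaining ribosomes for codons ending in G or C was tested as a hypothesis, since altered ribosomal RNA methylation might favour some codons. Across 8641 genes without histones, Spearman's rho of the log2 fold change with GC content at the last codon position was -0.00056 (0.01 with histones). Footprint totals of genes therefore did not shift with the share of such codons. These totals combine mRNA amount and translation, and occupancy of single codons was not measured, so the value cannot decide on a codon preference.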
